A study of Mus musculus with 6 samples.

How the data were processed

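RNA sequencing of mouse kidney was analysed from 1 deposited table that covers 6 libraries. Per the labels, 3 libraries came from mice with floxed Ccnb1 alleles and a Cdh16-Cre transgene (labelled knockout), and 3 came from mice with the floxed alleles alone (control). Ccnb1 encodes cyclin B1, the partner of Cdk1 at entry into mitosis. The Cdh16 promoter (kidney-specific cadherin) drives Cre recombinase in renal tubular epithelium. Whole kidney also holds vessels, stroma and immune cells, in which this promoter is not active. Groups and replicate numbers were taken from the sample titles. Which Ccnb1 exons are floxed, the age and the strain background of the mice are not given in the sources used here. The labels do not say that the replicates are separate animals, so p-values measure the spread between these libraries, which may be partly technical. The labels' extraction protocol names both kidney and cultured cells and goes on to describe quantitative PCR; the tissue label is kidney. Library preparation and strandedness are not given in the sources used here.

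The authors deposited estimated counts, without normalization, for 128603 transcripts of 51905 Ensembl gene IDs, next to FPKM values for the same transcripts. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1 and Cuffdiff 2.2.1 and the build GRCm38, with no role or order; the program that made the estimated counts is not given in the sources used here. In the values, 87.8% of gene sums above 0 lay within 0.01 of a whole number, while transcripts that share a gene held fractions. The deposited FPKM values use the column total of the same table as their denominator, so they carry no further information on depth. A column named length in the deposited table holds the genomic span of a transcript, introns included, and was not used as a transcript length. Gene coordinates are those of the deposited table, 1-based, on GRCm38; 94.2% of the 51628 gene IDs also present in GENCODE M21 have the same start and end there. The depth was 16061435 to 21261226 counts per library, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.141 to 0.187 CPM (counts scaled to a common library total). Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

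Estimated counts were summed per gene symbol (97 symbols join several gene IDs) and rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 6 libraries, with TMM normalization, the default expression filter (minimum count 10), group as the only term and Benjamini-Hochberg adjustment over 15017 genes, two-sided, with adjusted p under 0.05 as the threshold. A fold change is log2 of labelled knockout over control, and its standard error (SE) is the fold change divided by the square root of the F statistic. CPM values are TMM-normalised, with mean ± SD over 3 libraries. The design fixed beforehand named limma on log2(FPKM + 1) as the main test unless the table held counts per sample; it held estimated counts, so the edgeR branch of that design was followed.

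Of 39 gene lists fixed before the data were examined (kidney cell types, immune cells, cell cycle, p53, senescence, ageing, fibrosis, inflammation, metabolism, sex and neighbouring tissues), 34 had at least 5 tested members. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 34 lists. A few members were matched to older symbols in the table (Ccn2 as Ctgf, H2ax as H2afx, Rigi as Ddx58). Gene Ontology terms of the deposited table with 10 to 500 tested members were to be tested for genes called in a direction only where 10 or more were called. Single values were also compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 against 3.

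The genes named were set by a rule fixed beforehand: Ccnb1; up to 12 called genes per direction whose groups do not overlap, at 2 CPM or more, leaving out symbols of the Gm, Rik and LOC kinds and mitochondrial rRNA and tRNA; where fewer than 5 were called in a direction, the 8 of lowest unadjusted p, named as not past the threshold; up to 4 members per list, called ones or otherwise the most abundant; and 18 genes of the study's question. The filters on level and on symbols were carried over to the genes of lowest p, which is a reading of the rule. A few members of lists that the rule names are not reported here.

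Alternatives were limma with trend on log2(FPKM + 1) with FPKM of at least 1 in 3 libraries, pseudocounts of 0.1 and 0.5, no filter, FPKM of at least 5, quantile normalization, median-of-ratios scaling, no trend and library quality weights; edgeR with the replicate number as a block and without a filter; DESeq2 1.42.0; and each library left out in turn. Sums per Ensembl gene ID, lists without Kap and Mcm6 (with the preset and with an estimated correlation) and lists without genes of chromosome 1 were added after seeing the data. Replicate libraries were compared by chi-square over genes, within groups only. The statistic per degree of freedom was 20.7 to 59.6, so no 2 libraries of the same group agreed within sampling noise. The code was tested on simulated counts for the knockout and control comparison, with 200 of 15017 genes changed: edgeR recovered 11.3% of genes changed 1.5-fold, 71.4% of those changed 2-fold and 94.1% of those changed 4-fold, with 2 false calls among 123, and made 0 calls when nothing was changed. The simulation used the trended dispersion, so these shares are optimistic for genes that vary more.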

Results

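The data were RNA-seq profiles of 6 mouse kidney libraries, 3 labelled Ccnb1 knockout (floxed Ccnb1 with Cdh16-Cre) and 3 controls (floxed Ccnb1 alone). The study asked what loss of cyclin B1 in tubular epithelium does to arrest of the cell cycle before mitosis, to kidney ageing and to fibrosis. Each library held between 16061435 and 21261226 estimated counts, and 15017 genes were tested. Within groups the libraries differed by far more than counting error. On the first principal component (28.6% of the variance) control 2 lay at -49.6 and the other libraries between -7.2 and 22.1. On the second (23.3%) the libraries labelled knockout lay between -29.7 and -8.2 and the controls between 7.4 and 37.2. Libraries were nevertheless almost as alike between groups (mean correlation 0.9745) as within them (0.9754).

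Ccnb1 transcripts were rare in all 6 libraries and were not lower in the libraries labelled knockout. Ccnb1 (ENSMUSG00000041431, chromosome 13, 100778650 to 100786570, GRCm38) had 18, 15 and 11 estimated counts in the libraries labelled knockout and 11, 17 and 7 in the controls. These correspond to 0.832 ± 0.286 CPM against 0.646 ± 0.227 CPM (SD, n = 3 each). The log2 fold change was 0.34 (SE 0.46, 95% confidence interval -0.71 to 1.39; edgeR quasi-likelihood test, adjusted p = 0.9995), and an exact two-sided permutation test gave p = 0.5. The targeted gene therefore does not check the labels at this depth, and directions are given for libraries by label. The counts are per gene, and which exons are floxed is not given in the sources used here.

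The libraries labelled knockout contained no counts of Kap, the androgen-regulated kidney protein of proximal tubule. By mean count over the 3 controls, Kap was their second most abundant gene. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762) was listed at 0 in all 3 libraries labelled knockout, among 54629122 counts. The controls held 270761, 172207 and 284320 counts, or 13920 ± 4501 CPM (SD, n = 3). Against a floor of 3 counts per library (0.189 CPM at most), the lowest control of 8727 CPM was at least 46000-fold higher. Mcm6, a subunit of the helicase that unwinds DNA at replication, rose from 2.54 ± 0.777 to 25.1 ± 7.71 CPM (SD, n = 3). Mcm6 (ENSMUSG00000026355) lies on chromosome 1, 128331590 to 128359664, and its log2 fold change was 3.29 (SE 0.30).

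Kap and Mcm6 were the 2 genes past the threshold of the edgeR quasi-likelihood test, 1 lower (adjusted p = 0.00105) and 1 higher (adjusted p = 0.0331). The exact permutation p was 0.1 for each, the smallest that 3 against 3 allows. At an unadjusted p under 0.05 there were 485 genes, 203 higher and 282 lower, where chance alone gives 751. Groups did not overlap for 1228 genes, or 8.2%, against 10% by chance. DESeq2 called 15 genes, 13 of them higher. Mcm6 was not past the threshold with limma on log2(FPKM + 1) (adjusted p = 0.0726) or in the edgeR test without knockout 2 (0.0653), knockout 3 (0.189), control 1 (0.121) or control 3 (0.241), although its log2 fold change was 2.36 in that limma fit and 3.06 to 3.28 in these edgeR fits, while Kap was called in every alternative fit.

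**Figure D1:**
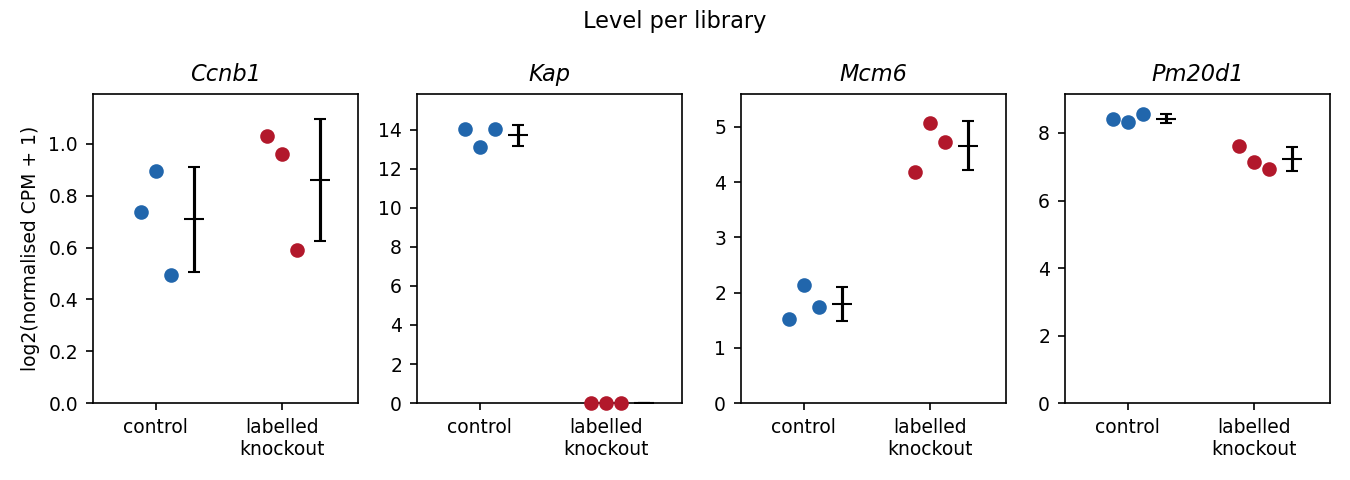
Levels of Ccnb1, Kap, Mcm6 and Pm20d1 in each library as log2(normalised CPM + 1), with 3 control and 3 labelled knockout libraries as points and the mean ± SD as bars. Kap sits at 0 in the 3 libraries labelled knockout, Mcm6 is higher in these 3 than in any control, and Ccnb1 overlaps between the groups.

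Among the genes of lowest unadjusted p that were higher by label, none of which passed the threshold, several code for immune receptors. Fcer1g and Fcgr3, the shared gamma chain and an activating receptor for immunoglobulin G on myeloid cells, had log2 fold changes of 1.76 (SE 0.31) and 1.47 (SE 0.29). The inhibitory receptor Fcgr2b stood at 0.80 (SE 0.17) and the leukocyte surface receptor Slamf7 at 1.86 (SE 0.40). Cfap126, a gene of motile cilia, reached 2.72 (SE 0.43), from 0.445 ± 0.123 to 2.99 ± 1.18 CPM (SD, n = 3), and the phosphatase Dusp23 reached 1.66 (SE 0.31). The glucuronosyltransferase Ugt2b37 was at 1.31 (SE 0.28) and Spc25, a kinetochore component, at 0.61 (SE 0.13). The 6 genes Fcer1g, Fcgr3, Fcgr2b, Slamf7, Cfap126 and Dusp23 lie on chromosome 1, as does Mcm6. Fcgr and Ugt2b genes belong to families of similar sequence, among which the authors' counting could divide reads.

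Genes of lowest unadjusted p that were lower by label, again not past the threshold, were led by Pm20d1, an enzyme that joins and cleaves N-acyl amino acids. Pm20d1, also on chromosome 1, stood at 152 ± 37.4 against 344 ± 30.8 CPM (SD, n = 3), a log2 fold change of -1.18 (SE 0.18; edgeR adjusted p = 0.547). Gnmt, the glycine methyltransferase that uses S-adenosylmethionine, was at -0.51 (SE 0.10). The extracellular matrix genes Frem1 and Ecm1 were at -0.92 (SE 0.21) and -0.65 (SE 0.15). The sphingosine-1-phosphate receptor S1pr3 was at -0.93 (SE 0.22), the ubiquitin ligase Rnf152 at -0.60 (SE 0.15) and the class I histocompatibility gene H2-Q6 at -0.68 (SE 0.17). AY036118, a transcript without a named product, was at -1.36 (SE 0.34). DESeq2 called Pm20d1 lower, and Cfap126, Dusp23, Ugt2b37 and Fcgr2b higher, with adjusted p between 4.44e-07 and 0.0491. In the simulation, however, DESeq2 made 14 false calls among 146. Pm20d1 was also called by edgeR without a filter on low counts (adjusted p = 0.0212) and by limma with library quality weights (0.0405). It was not called in the remaining alternatives.

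For fibrosis, matrix genes stood lower, not higher, in the libraries labelled knockout. Of 31 tested members of the extracellular matrix and fibrosis list, 29 were lower, with a median log2 fold change of -0.35, and none passed the gene threshold over all genes or adjusted over the list alone. The interstitial collagens Col1a1 and Col3a1 were at -0.45 (SE 0.17) and -0.39 (SE 0.26; -0.07 without control 1 and -0.62 without control 2), fibronectin (Fn1) at -0.43 (SE 0.22; -0.28 without control 3 and -0.62 without knockout 1) and Acta2, the smooth muscle actin of myofibroblasts, at -0.65 (SE 0.23). The more abundant basement membrane collagens Col4a1 and Col4a2 were at -0.07 (SE 0.11) and -0.04 (SE 0.14), Sparc at -0.03 (SE 0.11) and Ctgf at -0.23 (SE 0.18; -0.07 without knockout 2 and -0.40 without knockout 1). Vim, an intermediate filament of mesenchymal cells, was at -0.20 (SE 0.13; -0.13 without knockout 2). The list shifted down by camera with the preset correlation (adjusted p = 9.35e-11), but not with an estimated correlation (adjusted p = 0.564), and its median was -0.54 without knockout 1.

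Fibroblast and pericyte markers gave the same direction, with 8 of 10 lower and a median of -0.35 (camera adjusted p = 0.0015; adjusted p = 0.672 with an estimated correlation). Dcn, a matrix proteoglycan, was at -0.58 (SE 0.24) and Pdgfrb at -0.38 (SE 0.16), while Rgs5 and Ren1, genes of pericytes and renin cells, were at 0.31 (SE 0.21) and 0.39 (SE 0.34). The fibroblast call was lost in limma on log2(FPKM + 1) (median -0.14, adjusted p = 0.158), with library quality weights (0.04, 0.603) and without knockout 3 (adjusted p = 0.142) or control 2 (0.105, median -0.17). Genes of the TGF-beta pathway had a median of -0.03 over 17 members and a mean of -0.16 (camera adjusted p = 0.03; adjusted p = 0.672 with an estimated correlation), and that call was lost without any 1 of the knockout libraries or control 3 (adjusted p from 0.099 to 0.47), with a median of -0.19 without knockout 1. Tgfb1 was at 0.03 (SE 0.18), Ski at -0.03 (SE 0.12) and Tgfbr2 at -0.02 (SE 0.09). Tubular injury markers did not pass (17 members, median -0.05, camera adjusted p = 0.73), with Havcr1 at 0.80 (SE 0.85), Lcn2 at 0.71 (SE 0.59) and Spp1 at 0.12 (SE 0.16). Havcr1 was at -0.57 without knockout 3 and 1.86 without control 3, and Lcn2 at 0.24 without knockout 1, 0.32 without control 3 and 1.54 without control 2.

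For the cell cycle, mitotic genes did not pass any test. The 20 tested G2/M and mitosis genes other than Ccnb1 had a median log2 fold change of 0.16, 13 higher and 7 lower (camera adjusted p = 0.418). Ccnb2 was at 0.18 (SE 0.55; -0.56 without knockout 1), Cdk1 at -0.29 (SE 0.56; 0.03 without knockout 2), Mki67 at -0.09 (SE 0.26) and Top2a at 0.16 (SE 0.40), and these genes lay near 1 to 4 CPM. G1/S and DNA replication genes shifted up by camera (20 members, median 0.07; adjusted p = 0.00363, and adjusted p = 0.672 with an estimated correlation), a call that rested on Mcm6 and ended without Kap and Mcm6 (adjusted p = 0.4) or without control 3 (0.206, median -0.03), while the median was 0.18 without control 2. Among the other replication genes, Mcm7 was at 0.19 (SE 0.14) and Pcna at -0.13 (SE 0.09).

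Targets of p53 stood higher, with 19 of 24 above 0 and a median of 0.17. The list shifted up by camera (adjusted p = 0.0015; adjusted p = 0.304 with an estimated correlation), with a median of 0.11 without knockout 3 (camera adjusted p = 0.0257), and no member passed the threshold over all genes or adjusted over the list alone. Ccng1 was at 0.29 (SE 0.11), Perp at 0.26 (SE 0.12), Cdkn1a, the inhibitor of cyclin-dependent kinases, at 0.63 (SE 0.39; 0.08 without knockout 3) and Mdm2 at 0.02 (SE 0.16), and Trp53 itself was at -0.02 (SE 0.13). DNA damage repair genes had a median of 0 over 13 members (camera adjusted p = 0.616), with Atr at 0.05 (SE 0.11) and H2afx at 0.18 (SE 0.17). Senescence-associated secretory genes were mostly lower without passing (13 of 16, median -0.18, camera adjusted p = 0.0539), with Igfbp5 at -0.27 (SE 0.10) and Igfbp7 at -0.02 (SE 0.17). The 11 ageing genes had a median of -0.02 (camera adjusted p = 0.73). Kl, the ageing suppressor klotho, was at 0.07 (SE 0.12). Cdkn2a was too rare to test, with 12 counts in knockout 1 and 0 in the other 5 libraries.

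The proximal tubule list shifted down by camera (16 members, median -0.06; adjusted p = 1.23e-10, and adjusted p = 0.304 with an estimated correlation), but without Kap and Mcm6 the median of the other 15 was -0.04 and the adjusted p 0.723. With Kap, the median ran from -0.19 without control 2 to 0.02 without control 1. The transporters Slc34a1 and Slc27a2 were at -0.04 (SE 0.17) and 0.05 (SE 0.13). The epithelial cadherin genes Cdh16, whose promoter drives the Cre, and Cdh1 were at 0.06 (SE 0.12) and -0.01 (SE 0.10). Medians were 0.07 for thick ascending limb (Umod 0.14, SE 0.12; camera adjusted p = 0.199) and -0.05 for distal convoluted tubule (Slc12a3 -0.07, SE 0.12; 0.382). They were -0.06 for principal cells (Aqp2 -0.27, SE 0.30; camera adjusted p = 0.557), -0.13 for intercalated cells (Slc26a4 -0.14, SE 0.14; 0.117), -0.01 for podocytes (Podxl -0.14, SE 0.14; 0.987) and -0.10 for endothelium (Kdr -0.09, SE 0.15; 0.117).

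Macrophage and monocyte markers stood higher in all 16 tested members, with a median of 0.29. The list shifted up by camera (adjusted p = 1.17e-06; adjusted p = 0.564 with an estimated correlation), with a median of 0.17 without knockout 1 (camera adjusted p = 0.0203). Lyz2 was at 0.58 (SE 0.30), C1qa, a chain of complement C1q, at 0.55 (SE 0.26), Ctss at 0.15 (SE 0.17) and Csf1r at 0.12 (SE 0.11). T cell markers (11 members, median 0.26, camera adjusted p = 0.444; Lck -0.29, SE 0.29) and B and plasma cell markers (6 members, median -0.62, 0.382; Igkc -0.81, SE 0.52) did not pass. Interferon-stimulated genes (median -0.20, camera adjusted p = 0.261; Stat2 -0.25, SE 0.22), antigen presentation genes (-0.18, 0.382; B2m -0.22, SE 0.27), complement genes (-0.06, 0.433) and NF-kappa-B response genes (-0.16, 0.101; Nfkbia -0.17, SE 0.21) did not pass either.

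Fatty acid oxidation genes stood slightly higher, with 15 of 23 above 0, a median of 0.13 and a mean of 0.01 (camera adjusted p = 0.0208; adjusted p = 0.672 with an estimated correlation). Acadm and Ehhadh, enzymes of mitochondrial and peroxisomal oxidation, were at 0.21 (SE 0.15) and 0.28 (SE 0.19), and the call was lost without knockout 3 (adjusted p = 0.771, median 0.06) or control 1 (0.305). Cholesterol synthesis genes were lower in 15 of 20, with a median of -0.15 (camera adjusted p = 0.0376; adjusted p = 0.672 with an estimated correlation). Its abundant members went both ways, with Hmgcs1 at 0.22 (SE 0.17), Cyp51 at 0.38 (SE 0.10) and Srebf2 at -0.13 (SE 0.10), and the call was lost with the replicate block (adjusted p = 0.0578) and without knockout 1, knockout 3, control 1 or control 3 (adjusted p from 0.0565 to 0.553, the last with a median of -0.09). Oxidative phosphorylation genes (25 members, median 0.06, camera adjusted p = 0.0539; Atp5b 0.06, SE 0.13) and glycolysis genes (16 members, -0.03, 0.506; Ldha 0.11, SE 0.15) did not pass.

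Immediate early and stress genes stood lower, with 12 of 15 below 0 and a median of -0.64 (camera adjusted p = 0.0208; adjusted p = 0.837 with an estimated correlation). This rested on control 3, in which the heat shock gene Hspa1a stood at 792 CPM against 13.9 to 99.4 in the other 5 libraries, and the transcription factor gene Egr1 at 439 CPM against 22.3 to 50.7. Without control 3 the list turned to a median of 0.31 and shifted up (camera adjusted p = 3.25e-05), without control 2 the median was -1.02, and without knockout 1 the call was lost (adjusted p = 0.0583). Erythroid genes had a median of -0.26 over 6 members (camera adjusted p = 0.0225; adjusted p = 0.698 with an estimated correlation), with Hbb-bs at -0.10 (SE 0.24) and Slc4a1 at -0.57 (SE 0.17). The erythroid call was lost with library quality weights (median 0.04, camera adjusted p = 0.543), in edgeR without a filter (0.0573) and without knockout 1, knockout 3, control 1 or control 2 (adjusted p from 0.101 to 0.327), and the median ran from -0.41 without control 3 to -0.09 without control 1.

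Genes higher in male kidney had a median of 0.29 over 12 members, with 8 higher, yet camera called the list down (adjusted p = 0.0015; adjusted p = 0.698 with an estimated correlation). The mean was -1.02 with Kap at its bound. Without Kap the other 11 had a median of 0.31 and shifted up (camera adjusted p = 0.000823), but not with an estimated correlation (adjusted p = 0.822), with Cyp2e1 at 0.33 (SE 0.18), Acsm3 at 0.62 (SE 0.66) and Cndp2 at -0.46 (SE 0.52). The downward call was lost without knockout 1 (adjusted p = 0.327), control 1 (0.119) or control 3 (0.0627), and the median was 0.08 without knockout 2 or without control 2 and 0.45 without knockout 1. Control 2 held 134 CPM of Acsm3 against 957 to 1620 in the other 5 libraries. Genes higher in female kidney had a median of -0.03 (10 members, camera adjusted p = 0.987), with Cyp2a4 at 0.19 (SE 0.18). The Y-linked gene Ddx3y was present at 43.3 to 71.5 CPM in all 6 libraries, and Xist had at most 9 counts in any. The 4 Y-linked genes had a median of 0.13, too few to test as a list, and the female-linked list had no tested member.

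Markers of neighbouring tissues did not pass, with medians of -0.36 for adipose tissue (6 members, camera adjusted p = 0.621; Fabp4 -0.19, SE 0.16) and -0.02 for urothelium (8 members, 0.987; Upk1a 0.11, SE 0.32). Adrenal, skeletal muscle and neutrophil lists had 1, 2 and 2 tested members and were not tested, with Star at -0.02 (SE 0.28), Actn3 at -0.21 (SE 0.44) and Csf3r at -0.19 (SE 0.38). Adjusted over the list alone, 4 genes passed in any list, namely Kap, Mcm6, the macrophage list's Fcer1g (edgeR adjusted p = 0.00679) and the male list's Ugt2b37 (0.00986), against Kap and Mcm6 over all genes. In all, camera called 12 of 34 lists with the preset correlation, 4 up and 8 down. None passed with an estimated correlation (lowest adjusted p = 0.304) or by fry for a shared direction (lowest adjusted p = 0.202), and these numbers stand beside 485 genes at an unadjusted p under 0.05. The fry test for changes in either direction passed for the 3 lists that hold Kap or Mcm6, namely male (adjusted p = 0.000192), proximal tubule (0.000276) and G1/S (0.00493).

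**Figure D2:**
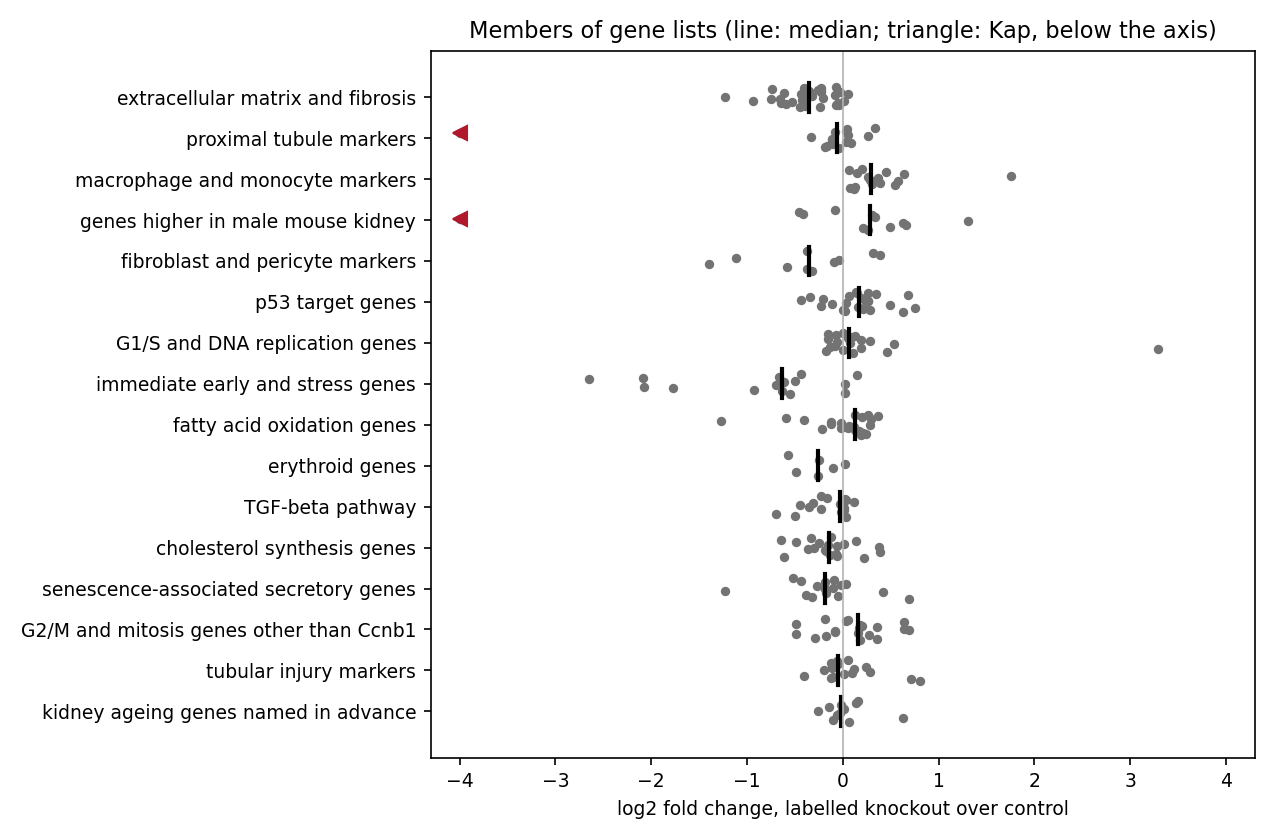
Log2 fold change (labelled knockout over control) of each tested member of 16 gene lists, with 1 point per gene and a line at the list's median; triangles mark Kap, which lies beyond the axis. Matrix genes centre at -0.35 and macrophage markers at 0.29, and Mcm6 stands apart from the other replication genes.

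Gene Ontology terms were not tested among called genes, since 1 gene was called in each direction. Among the 68 genes at an unadjusted p under 0.01, 35 higher and 33 lower, 0 of 5704 tests of terms in either direction passed (Fisher's exact test, lowest adjusted p = 0.502). These 68 genes were unevenly placed on the genome, a feature examined after the values were seen. Of them, 23 lie on chromosome 1, which carries 897 of the 15017 tested genes, and 14 lie between 170 and 175 Mb of it. That window holds 71 tested genes, so 19.7% of them had such a p, against 0.45% of all genes. Of the 14, 13 were higher, among them Fcer1g, Fcgr3, Fcgr2b, Slamf7, Cfap126 and Dusp23.

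**Figure D3:**
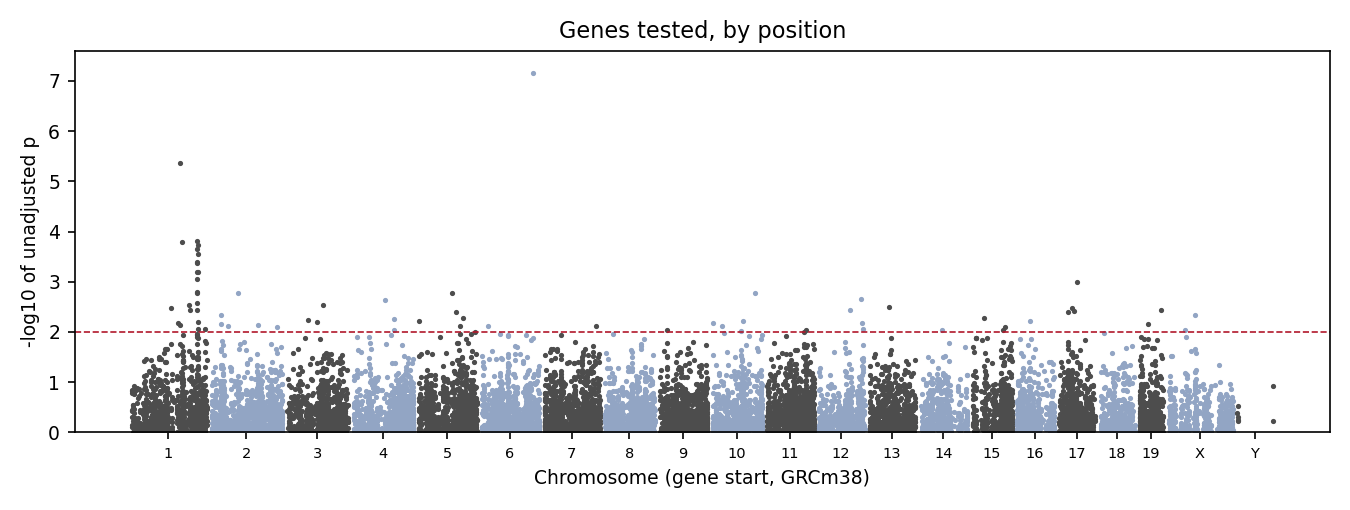
The -log10 of the unadjusted p of each tested gene against the position of its start on GRCm38, with chromosomes in alternating shades and a dashed line at the level of 0.01. The column of points near the end of chromosome 1 holds the 14 genes between 170 and 175 Mb, and the 2 highest points are Kap on chromosome 6 and Mcm6 on chromosome 1.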

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

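The comparison below was chosen after the values were seen. A Ccnb1 transcript with a retained intron (ENSMUST00000128279, chromosome 13, 100783044 to 100785603, GENCODE M21 on GRCm38) is part of the gene sums but was not compared alone, and it held 3, 1 and 2 estimated counts in the libraries labelled knockout, 6 in all, and 0 in the controls. It was picked from the 7 Ccnb1 transcripts for this difference, so no test is given. Another of them, ENSMUST00000174038, went the other way, with 2.15 counts against 7.38.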

How the results depend on the processing

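Of the settings below, 4 were chosen after seeing the data: sums per gene ID, lists without Kap and Mcm6 with the preset and with an estimated correlation, and lists without genes of chromosome 1. Kap stayed past the threshold in every alternative. Against 2 genes called by edgeR (1 higher, 1 lower), limma on log2(FPKM + 1) called 1 gene (0 higher), and so did limma with log2(FPKM + 0.1), log2(FPKM + 0.5), no filter on low values, FPKM of at least 5, quantile normalization, median-of-ratios scaling and eBayes without trend, each 1 gene and 0 higher. Library quality weights gave 3 genes (1 higher, 2 lower), edgeR without a filter on low counts 5 genes (3 higher, 2 lower) and DESeq2 15 (13 higher, 2 lower). Leaving out 1 library gave 1 (without knockout 3, control 1 or control 3) to 6 genes (without knockout 1), 0 to 2 higher and 1 to 4 lower. Sums per gene ID gave 2 genes. The replicate block gave 2 genes and 11 lists, without cholesterol synthesis (camera adjusted p = 0.0578). Deviations of same-numbered libraries correlated at 0.09, -0.09 and 0.12, and 4 of 6 libraries correlated best with their own number. The labels do not state a pairing, and these few values do not settle whether the numbers pair the libraries. Ccnb1 stayed above 0 and not called, from 0.10 to 0.61 without 1 library; the FPKM filters removed it. The cause was not tested for any of these differences.

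Against 12 lists called by camera, limma on log2(FPKM + 1) and eBayes without trend gave 7, quantile normalization 6, and log2(FPKM + 0.1), log2(FPKM + 0.5) and median-of-ratios scaling 4 each. The totals of 7 and 6 include lists outside these 12, so fewer of the 12 stayed called than the totals show. Lists without genes of chromosome 1 gave 10, without the TGF-beta (adjusted p = 0.0569) and G1/S calls (0.552), and lists without Kap and Mcm6 gave 10. An estimated correlation gave 0, also without Kap and Mcm6, and fry 0. DESeq2 gives no log values for camera and was not run for lists. The matrix, macrophage and p53 calls ended only with an estimated correlation or fry. In limma on log2(FPKM + 1) the calls of the proximal tubule (adjusted p = 0.0678), TGF-beta (0.0608), G1/S (0.141), cholesterol (0.0573), immediate early (0.106) and fibroblast lists (0.158, median -0.14) were lost. Library quality weights left the fibroblast and erythroid lists at 0.04 each, not called (0.603 and 0.543), and edgeR without a filter on low counts lost the TGF-beta, cholesterol and erythroid calls (0.0573 each). The G1/S list was at -0.02 with FPKM of at least 5. The list of genes higher in male kidney, called down through Kap with a median of 0.29, took the direction up without being called (adjusted p from 0.218 to 0.822), with a median of 0.33 in limma on log2(FPKM + 1), with log2(FPKM + 0.1), log2(FPKM + 0.5), no filter on low values, FPKM of at least 5, median-of-ratios scaling and eBayes without trend, of 0.28 with quantile normalization and 0.25 with library quality weights. Without Kap and Mcm6 its median was 0.31, called up with the preset correlation (adjusted p = 0.000823) and not with an estimated one (0.822). Kap itself was at -14.20, -15.20 and -17.52 in limma with 1, 0.5 and 0.1 added to FPKM and at a fitted -20.94 in edgeR, since the value of a gene at 0 is set by the constant added. Over the called lists, 140 values under alternatives stayed called in the same direction, 111 were no longer called and 12 reversed.

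Some genes that were not called changed sign. With library quality weights Cdk1 was at 0.01, Tgfb1 at -0.03, Havcr1 at -0.04 and Cdh1 at 0.08. Without 1 library Ccnb2 ranged from -0.56 to 0.54, Cdk1 from -0.83 to 0.03, Tgfb1 from -0.12 to 0.15, Havcr1 from -0.57 to 1.86, Cdh16 from -0.01 to 0.12, Cdh1 from -0.06 to 0.05 and Trp53 from -0.13 to 0.04, and the immediate early list from -1.02 to 0.31. Others kept their sign but moved by over 1.5 times, with Cdkn1a from 0.08 to 0.93, Col3a1 from -0.62 to -0.07, Fn1 from -0.62 to -0.28, Ctgf from -0.40 to -0.07, Vim from -0.29 to -0.13, Lcn2 from 0.24 to 1.54 and Kl from 0.01 to 0.13. Of the values of single genes under alternatives, 578 kept direction and side of the threshold, 12 (all Mcm6) were no longer called, 7 became called and 15 changed sign. Terms among genes at unadjusted p under 0.01 numbered 0 with all libraries, with FPKM of at least 5 and with the block, 11 without knockout 1 (among them extracellular matrix, adjusted p = 0.000126, basement membrane and collagen binding, in lower genes), 13 without control 2 (among them terms of MHC class I and immunoglobulins) and 1 without control 3. With 7 to 18 counts per library, the interval of Ccnb1 ran from -0.71 to 1.39.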

Other observations

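The tests of explanations in this part were chosen after the results were seen, and so were the genes named here that the report does not name, while the edgeR and DESeq2 calls were planned. The window from 170 to 175 Mb of chromosome 1 carried further genes that stood apart by label, with none past the threshold of the edgeR test. Among its 15 calls, DESeq2 called Gm7694, Gm9929, Fcgr2b, Cfap126, Dusp23, Ifi206 and Ifi213 in this window, and edgeR without a filter on low counts called Ifi213. Both also called 3110045C21Rik, which starts just before the window at 169969409. It stood at 8.03 ± 6.03 against 0.514 ± 0.137 CPM (SD, n = 3). Sdhc, a subunit of mitochondrial complex II, was at 372 ± 26.7 against 266 ± 27.4 CPM (SD, n = 3; log2 fold change 0.48, SE 0.12), and the coatomer gene Copa at 326 ± 33.1 against 245 ± 11.5 CPM (0.41, SE 0.11). Klhdc9 was at 1.29 (SE 0.30). The interferon-inducible genes Ifi206 and Ifi213 were at 1.08 ± 0.387 and 1.97 ± 1.20 CPM against 0 and 0.0371 ± 0.0325, while the neighbouring Ifi202b went the other way, with a log2 fold change of -2.44 (SE 0.71). These Ifi genes are similar in sequence, so reads could be divided among them by the authors' counting. Dars, next to Mcm6, was at 0.43 (SE 0.12).

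Single control libraries also stood apart in some genes, picked here for that reason. Control 2 held 280 CPM of Cyp4a14, a fatty acid hydroxylase, against 11.96 to 57.9 in the other 5 libraries, and 68.4 CPM of the organic anion transporter Slco1a1 against 416 to 856. Control 3 held 32.3 CPM of the stress factor Atf3 against 1.72 to 3.23, and 1244 CPM of Hspa1b against 46.5 to 226.

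Genes with an unadjusted p under 0.01 were crowded at 170 to 175 Mb of chromosome 1, with 14 genes in the window. More macrophages as a cause stays open for the immune receptor genes among them. The comparison did not cover the other genes of the window, such as Sdhc and Copa. The 15 macrophage markers on other chromosomes were all higher, with a median of 0.28 (interquartile range 0.28) and at most 0.64. The lowest of Fcer1g, Fcgr3, Slamf7 and Fcgr2b was at 0.80. These immune receptor genes were named for their low p in the same data, which favours large values, so the comparison cannot decide. A candidate explanation is a segment of different genetic background in the libraries labelled knockout, for instance one that travels with the Cre transgene: of the 57 other genes in the window, 16 had groups that do not overlap (28.1%, against 7.7% of such genes elsewhere). The fullest windows of the other splits reached up to 24.1%, so this stays a hypothesis. An extra copy of the segment stays open. The median of all 71 genes was 0.20, with 52 of them higher and an interquartile range of 0.62. That range is the spread of single genes and not the error of the median, and an extra copy of only part of the window was not tested. An effect of Ccnb1 deletion stays open too, as it was not tested apart from the Cre.

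Kap was listed at 0 in the 3 libraries labelled knockout. A general loss of the androgen response would lower the other 11 genes of the male list together, and their values argue against it. They went both ways, with 8 higher, a median of 0.31 (interquartile range 0.49) and the lowest at -0.46. The median stayed above 0 with any 1 library left out. It ran from 0.10 without knockout 2 and 0.12 without control 2 to 0.46 without knockout 1. This covers the genes of that list, not a loss confined to Kap. A locus left without an estimate by the authors' quantification may remain, although 0 other genes were at 0 in all libraries of one group with 200 or more counts in each of the other. A segment of different background around Kap had no sign beyond Kap itself, with 0 of 51 genes within 5 Mb at an unadjusted p under 0.01, but a change in Kap alone, such as a deletion of the gene, cannot be told apart from these without reads. An effect of Ccnb1 deletion stays open and untested.

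The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2 genes and the highest other split 2, so 2 splits gave as many. It gave 12 lists and the highest other split 18, with 5 splits at 12 or more. Its fullest window held 14 genes of low p of 71 (19.7%) and that of the highest other split 9 of 38 (23.7%, a higher share), so 1 split, the real one, reached 14.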
